A study of Mus musculus with 12 samples.

How the data were processed

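Dorsal and ventral hippocampus of adult mice were macrodissected, per the series' design text. RNA was extracted with Trizol and libraries were made from 500 ng of total RNA with a QuantSeq 3′ mRNA-Seq kit, per the labels. Tamoxifen was given from 6 weeks of age at 50 mg/kg, 2 injections a day for 5 days, then after a break of 7 days for 5 more days, per the labels. The Cre line came from a mixed B6;129S6 background and the floxed line from C57BL/6N, per the series' design text. Each group held 3 samples, and each sample was sequenced in 3 runs except dorsal cKO 64, which had 2 (17 dorsal and 18 ventral runs). The labels describe the groups as mice but do not state that the number in a sample's title is an animal's number. It is read so here, since the numbers are not consecutive and the 4 numbers that occur in both regions (40, 41, 49 and 64) carry the same genotype in both.

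The deposited table of each region holds whole-number counts per gene and run, and per the submitters' processing notes reads went through cutadapt, HISAT2 and featureCounts on GRCm38. Versions, the annotation release and the strand setting of the counting were not given in the sources used here, so reads of overlapping or antisense genes, such as mt-Nd6 opposite mt-Nd5, cannot be told apart. The tables also hold a scaled signal per gene and run, made by the authors by scaling counts to library size (CPM), which was not tested. Per the file headers the authors' comparison of cKO with control gives a log2 fold change and a log2 CPM per gene, a likelihood ratio score, a p-value and a false discovery rate from edgeR. In the deposited tables, the authors' marks for up and down were found to need a false discovery rate under 0.05 and a log2 fold change beyond 1 in size. There are 29407 genes for the dorsal and 29146 for the ventral hippocampus, with 26787 in both and 31766 in either. Of these identifiers 31713 (99.83%) were found in GENCODE M21, an annotation of GRCm38, from which coordinates were taken.

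Counts were summed over the runs of each sample, so that a sample counts once. Totals were 5.12 to 15.9 M per sample (median 9.07 M) and 1.07 to 7.17 M per run. The chi-square per gene was 1.18 to 8.04 between runs of one sample (median 3.05, 34 pairs) and 3.71 to 9.04 between samples of one group (median 6.32, 12 pairs), so every pair differed by more than sampling noise alone would give. On the first principal component (26.8% of variance over 16414 genes) the samples parted by region. The ventral cKO samples (7.5 to 20.6) lay nearer the dorsal samples on it than the ventral controls did (25.3 to 32.5). Ventral genotype and position on this component are therefore not told apart, and the cause of the shift was not tested. The next components held 16 and 9.8%.

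Genotype was tested per region, and the interaction and the region difference in 1 fit of all 12 samples, with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, TMM scaling, filterByExpr by group and Benjamini-Hochberg adjustment at 0.05. This left 15692 dorsal, 15102 ventral and 16414 joint genes. The median SE of a log2 fold change was 0.151 in the dorsal, 0.161 in the ventral, 0.238 in the interaction and 0.119 in the region comparison, which is the precision that this depth and number of samples gave. Levels are CPM with the SD between samples, and fold changes carry the SE of the fit. With 3 samples against 3, an exact permutation test cannot go below p = 0.10, so no such test was used for single values. An alternative for each result was DESeq2 1.42.0 or voom of limma 3.58.1. Others were other scalings, no or a stricter filter (a mean of at least 10 counts), single runs, runs as separate libraries, and each sample left out in turn.

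Gene lists of brain cell types, hippocampal subfields, neighbouring tissues, signalling and cell functions, 42 in all with at least 3 tested members, were tested with limma's camera on log2 CPM (prior count 3) with a preset correlation of 0.01. Each was repeated with an estimated correlation and with fry. Lists, groups, tests and alternatives were fixed before the data were examined, except where a setting is said to have been chosen after the data were seen. Genes are named by a rule fixed with them. It takes Tet1, Tet2 and Tet3, the 10 lowest p per genotype comparison where fewer than 10 passed, and the 4 lowest p per list described. It adds the 5 lowest p of the interaction, the 5 largest changes toward each region at 1 CPM or more, and the dorsal and ventral markers. Genes named from the DESeq2 calls, from the authors' deposited tables, and Ttr were chosen after their values were seen.

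Samples with the same number come from the same animal on the reading above, and p-values rest on the samples of a group being separate animals. Their deviations from the group means correlated at 0.035 (40), 0.106 (41), 0.076 (49) and -0.107 (64) between regions, and the consensus correlation within a number was 0.058. The genotype groups of a region share no number. With the number as a block, only the numbers found in both regions inform the region and interaction comparisons. The interaction then sets cKO 40 and 64 against controls 41 and 49, with few residual degrees of freedom. A call lost with the block can therefore come from less data as well as from pairing. The gene tests were tried on simulated counts drawn from the real means, library sizes and edgeR's dispersion estimates per gene, with 200 genes changed. Each gene was drawn independently, so variation shared among genes was left out and recovery in the real data can be lower. The adjustment is also easier to pass when many genes change. The shares therefore hold for 200 changed genes and can be lower with fewer. Changes of 1.5-, 2- and 4-fold were recovered in 40.3, 79.1 and 92.4% of genes in the dorsal comparison and in 31.3, 71.6 and 97% in the ventral comparison. The interaction recovered 13.4, 44.8 and 77.3% and the region comparison 53.7, 85.1 and 90.9%. False calls were 10, 12, 7 and 15 in these 4 comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.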

Results

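RNA from the dorsal and the ventral hippocampus of adult mice was profiled by 3′ end sequencing, in which each read is a tag from near the end of a polyadenylated transcript. Per the labels, the knockout animals (cKO) were homozygous for a floxed Tet3 allele and carried a tamoxifen-inducible Cre recombinase under the Camk2a promoter, which is active in excitatory forebrain neurons. The controls carried the floxed alleles without Cre. Each of the 4 groups (dorsal control, dorsal cKO, ventral control, ventral cKO) held 3 samples, sequenced in 35 runs and counted here as 12 samples. Total counts were 8.98, 9.16 and 9.3 M in the dorsal controls 41, 49 and 71, and 11.4, 10.68 and 5.12 M in the dorsal cKO samples 40, 43 and 64. The ventral controls 41, 49 and 50 held 15.9, 7.08 and 7.95 M, and the ventral cKO samples 40, 63 and 64 held 9.21, 7.35 and 6.69 M. Mitochondrially encoded transcripts took 4.02 to 4.83% of counts in the dorsal controls and 3.64 to 3.81% in the dorsal cKO samples. Their share was 3.63 to 4.36% in the ventral controls and 3.34 to 4.48% in the ventral cKO samples.

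Tet3, the targeted gene, encodes a dioxygenase that oxidises 5-methylcytosine in DNA. The gene (ENSMUSG00000034832) lies on the minus strand of chromosome 6 from 83362373 to 83459084 in GRCm38. Its level was 29.82, 37.47 and 33.9 CPM (counts scaled by library size) in the dorsal controls 41, 49 and 71, and 32.38, 41.7 and 40.85 CPM in the dorsal cKO samples 40, 43 and 64. In the ventral hippocampus it was 34.73, 30.49 and 23.37 CPM in the controls 41, 49 and 50, against 35.04, 25.11 and 32.2 CPM in the cKO samples 40, 63 and 64. The log2 fold change, cKO over control, was 0.18 ± 0.12 (SE, n = 3 per group) in the dorsal hippocampus and 0.05 ± 0.17 in the ventral hippocampus. Neither passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.968 and 0.963). The ventral value was below 0 without ventral control 50 (-0.09) and without ventral cKO 40 (-0.05). The position of the floxed exons was not given in the sources used here, and a 3′ tag outside the deleted part is counted from the recombined allele as well, so these levels check nothing about the deletion.

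**Figure D1:**
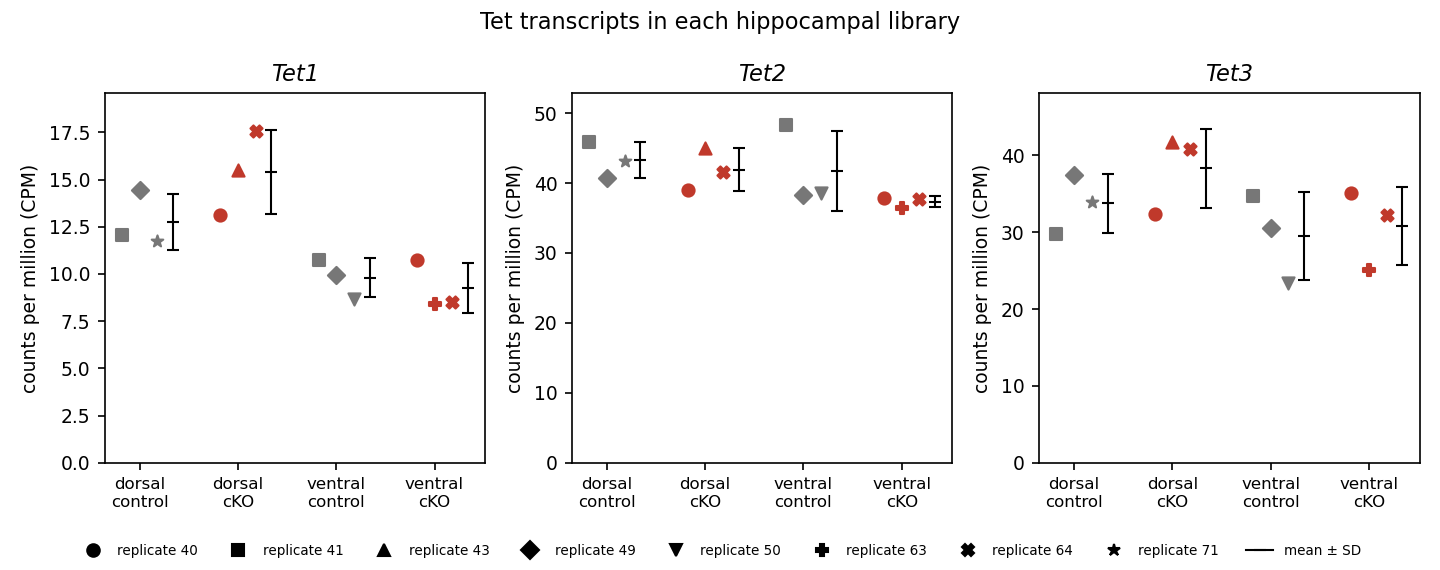
Level of Tet1, Tet2 and Tet3 in CPM in each of the 12 samples; marker shapes give the replicate number, grey marks controls and red marks cKO, and the bars give the mean and SD of 3 samples. Tet3 spans 29.82 to 37.47 CPM in the dorsal controls and 32.38 to 41.7 CPM in the dorsal cKO samples, so the groups overlap.

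The related enzymes Tet1 and Tet2 did not pass the test either. Dorsal Tet1 was 15.4 ± 2.22 CPM in cKO and 12.75 ± 1.48 CPM in control samples (SD, n = 3; log2 fold change 0.26 ± 0.16, SE), and dorsal Tet2 was 41.9 ± 3.03 against 43.23 ± 2.57 CPM. In the ventral hippocampus Tet1 was 9.237 ± 1.32 against 9.795 ± 1.03 CPM, and Tet2 37.33 ± 0.784 against 41.71 ± 5.69 CPM (log2 fold change -0.17 ± 0.12). Dorsal Tet1 was at 0.16 without cKO 64 and ventral Tet2 at -0.04 without control 41. Among the 24 tested genes of the DNA methylation machinery in the dorsal hippocampus, 2 had an unadjusted p under 0.05, both with higher values in cKO: Cxxc5 (0.31 ± 0.12), a zinc finger protein that binds unmethylated CpG, and Gadd45b (0.42 ± 0.19), a stress-inducible gene linked to DNA demethylation. In the ventral hippocampus 1 of 23 did, again Gadd45b (0.46 ± 0.20). The list was not called in either region (limma camera, adjusted p = 0.561 and 0.442).

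The first comparison asked which dorsal transcripts differ after Tet3 ablation. Transcripts of the mitochondrial genome had the smallest p of all lists: all 15 tested members had a lower mean in cKO, with a median log2 fold change of -0.46. mt-Nd5, a subunit of respiratory complex I, was at 506.6 ± 41.6 CPM in cKO and 774.3 ± 158 CPM in control samples (SD, n = 3; log2 fold change -0.61 ± 0.13, SE). The complex I subunits mt-Nd2 (-0.43 ± 0.09) and mt-Nd4 (-0.46 ± 0.11) and the cytochrome oxidase subunit mt-Co1 (-0.46 ± 0.11) had similar values. Lrpprc (ENSMUSG00000024120; chromosome 17, 84705247 to 84790789), a nuclear gene whose product binds and stabilises mitochondrial messenger RNAs, had the lowest p of all dorsal genes, at 151.6 ± 16.8 against 233 ± 31.8 CPM (-0.62 ± 0.11). The mitochondrial list was called lower (limma camera, adjusted p = 6.65e-12), but not when the correlation among its members was taken from the data (adjusted p = 0.785 with an estimated correlation). Adjusted over the list alone, 11 of the 15 members passed, and adjusted over all genes 0 did, while 12 had an unadjusted p under 0.05. As a score (mean log2 CPM of the members relative to the dorsal control mean), the 3 dorsal cKO samples lay at -0.43 ± 0.08 and the controls at 0 ± 0.21 (SD).

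Other nuclear gene groups with a lower ranking in dorsal cKO were those of protein synthesis and respiration. Of 86 cytosolic ribosomal protein genes, 70 had a lower mean in cKO (median -0.09, adjusted p = 8.52e-05), among them Rpl4 (-0.39 ± 0.11) and Rps24 (-0.34 ± 0.11). Of 88 nuclear oxidative phosphorylation genes, 63 did (median -0.06, adjusted p = 0.0139), among them Ndufa5 of complex I (-0.36 ± 0.11) and Sdhd of complex II (-0.35 ± 0.14). Another 3 lists ranked higher in cKO. The oligodendrocyte markers (19 tested, median 0.10, adjusted p = 0.0162) included Myrf, the transcription factor of myelin genes (0.50 ± 0.14), and Opalin, a myelin membrane protein (0.34 ± 0.13). The ependymal markers (7 tested, median 0.34, adjusted p = 0.0162) included Tmem212 (0.83 ± 0.28) and Ccdc153 (0.49 ± 0.17). The interferon response genes (27 tested, median 0.22, adjusted p = 0.0326) included Oasl2 (0.81 ± 0.41) and Trim30a (0.46 ± 0.25), with Psmb9 at -0.53 ± 0.26. Single samples moved some of these values: without cKO 40 Sdhd was at -0.16 and Oasl2 at 0.45, and without cKO 43 Psmb9 was at -0.31. None of these 5 lists was called with an estimated correlation (adjusted p = 0.79 for interferon response and 0.785 for the others, with an estimated correlation). Adjusted over the list alone, 2 ependymal markers passed and 0 members of the other 4 lists, and adjusted over all genes 0 did in each list. In the ribosomal list 8 members had an unadjusted p under 0.05, in the oxidative phosphorylation list 7, in the oligodendrocyte list 2, in the ependymal list 2 and in the interferon list 0.

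Leaving out single samples ended several of these list calls. At the preset correlation the mitochondrial and ribosomal lists stayed called whichever 1 of the 6 samples was left out, but with all 6 samples neither was called with an estimated correlation (adjusted p = 0.785 for both with an estimated correlation). For nuclear oxidative phosphorylation genes, dorsal calls were lost without control 41 (adjusted p = 0.0565), control 71 (0.121), cKO 43 (0.144) or cKO 64 (0.0706). For oligodendrocyte markers, dorsal calls were lost without control 41 (0.0625), control 71 (0.0715), cKO 40 (0.508) or cKO 43 (0.0644). For ependymal markers, dorsal calls were lost without control 41 (0.198), control 71 (0.124) or cKO 40 (0.0522), and for interferon response, dorsal calls were lost without control 41 (0.198), control 71 (0.0894) or cKO 40 (0.808). Choroid plexus markers, a sign of ventricular tissue in the dissected piece, differed widely among the dorsal samples of each genotype, with scores of -0.85, 2.45 and -1.60 in controls 41, 49 and 71 and of -0.76, -1.06 and 1.90 in cKO samples 40, 43 and 64. That list had a median of -0.52 over 13 members and a camera direction of up, and was not called (adjusted p = 0.987).

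Single dorsal genes were called or not depending on the tool. edgeR's quasi-likelihood test called 0 of 15692 genes (smallest adjusted p = 0.582), with 769 at an unadjusted p under 0.05, against 785 expected by chance; limma-voom called 0 as well. DESeq2 called 22 genes on the same counts, all lower in cKO, led by Lrpprc (DESeq2 adjusted p = 0.000673), mt-Nd5 (0.00206), mt-Nd2 and the ganglioside synthase St3gal5 (0.00261). Among the 10 genes with the lowest edgeR p were also Mcam, an adhesion molecule of vessel walls (-0.46 ± 0.09), Mt3, a zinc-binding metallothionein of the brain (-0.47 ± 0.10), and the clock-linked transcription factor Tef (-0.43 ± 0.09). Bok, a member of the BCL-2 family, was the single one of the 10 with a higher mean in cKO (0.45 ± 0.10). The remaining members, the pseudogene Gm13340 (-0.97 ± 0.19) and the predicted gene Gm10800 (-1.53 ± 0.32), have reads that can be shared with near-identical copies, so their values are uncertain. Without a filter on low counts edgeR called 94 dorsal genes, and without dorsal control 49 it called 25, of which 24 were lower. In simulated data of the same depth, 40.3% of genes changed 1.5-fold and 79.1% of genes changed 2-fold were recovered. Many changes below 2-fold were thus missed even with genes drawn independently, and in the real data larger ones can be missed too.

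The second comparison asked the same of the ventral hippocampus. Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, had the largest difference: all 15 tested members had a lower mean in cKO (median log2 fold change -1.86). Enpp2, a secreted lysophospholipase, was at 267.7 ± 253 CPM in cKO and 901.4 ± 138 CPM in control samples (SD, n = 3; -1.75 ± 0.47, SE). Sostdc1, an antagonist of BMP and Wnt signals (-1.86 ± 0.44), the prolactin receptor gene Prlr (-1.70 ± 0.49) and the collagen gene Col8a1 (-2.08 ± 0.61) had values of the same order. Without ventral cKO 63 they were -2.89 (Enpp2), -3.0 (Sostdc1), -3.05 (Prlr) and -4.36 (Col8a1). The list was called lower (limma camera, adjusted p = 1.53e-12), but not with the correlation taken from the data (adjusted p = 0.818 with an estimated correlation). Adjusted over the list alone 12 of 15 members passed, adjusted over all genes 0 did, and 13 had an unadjusted p under 0.05. The samples of one group were unlike each other: Ttr, the transthyretin gene and an abundant choroid plexus transcript, was at 59.33, 1864 and 40.74 CPM in the ventral cKO samples 40, 63 and 64, against 2937, 3352 and 2334 CPM in the controls. In the dorsal hippocampus it was at 157.64, 3384 and 41.33 CPM in the controls and 97.66, 67.23 and 1940 CPM in the cKO samples.

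Activity-regulated immediate early genes, which neurons induce within minutes of firing, ranked higher in ventral cKO. Of 39 tested, 31 had a higher mean (median 0.29), 13 at an unadjusted p under 0.05 and 1 in the other direction at that level. The transcription factor Egr1 was at 539.5 ± 49 CPM in cKO and 344.3 ± 73.2 CPM in control samples (0.65 ± 0.14). Nr4a1, a nuclear receptor (0.78 ± 0.25), Arc, which acts in AMPA receptor trafficking (0.71 ± 0.23), and the phosphatase gene Dusp6 (0.30 ± 0.10) were further members; Arc was at 0.45 without cKO 64. The list was called (limma camera, adjusted p = 5.73e-06), but not with the correlation taken from the data (adjusted p = 0.818 with an estimated correlation), with 1 member past the threshold adjusted over the list alone and 0 adjusted over all genes. Its score was 0.35 ± 0.09 in the cKO samples and 0 ± 0.28 in the controls, where control 49 reached 0.29.

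A further 4 lists were called in the ventral hippocampus. Interferon response genes ranked higher (23 tested, median 0.33, adjusted p = 0.0108), with Rtp4 at 0.70 ± 0.31 and Ifit3b at 0.46 ± 0.23. Ependymal markers ranked lower (7 tested, median -0.52, adjusted p = 0.0138), with the axonemal gene Rsph1 at -0.52 ± 0.22. Meningeal fibroblast markers ranked lower (12 tested, median -0.28, adjusted p = 0.0244), with Dcn, a small matrix proteoglycan, at -0.49 ± 0.13 and Igfbp2 at -1.09 ± 0.34. Markers of the ventral hippocampus ranked lower (11 tested, median -0.06, adjusted p = 0.0403), with Dlk1 at -0.47 ± 0.15 and Gpr101 at -0.49 ± 0.20; Dcn is a member of this list too. Without cKO 63 Rsph1 was at -0.82 and Igfbp2 at -1.80, without cKO 64 Rsph1 was at -0.34, and without cKO 40 Dlk1 was at -0.31. None of the 4 was called with an estimated correlation (adjusted p = 0.818 for each with an estimated correlation). Adjusted over the list alone, 2 meningeal and 1 ventral marker passed, all lower, and 0 members of the interferon and ependymal lists; adjusted over all genes 0 did. Counts at an unadjusted p under 0.05 were 1, 2, 3 and 3 for the interferon, ependymal, meningeal and ventral lists. The choroid plexus scores differed between the same groups: 0.20, 0.18 and -0.38 in the ventral controls, and -3.50, -0.42 and -3.97 in the cKO samples 40, 63 and 64. On the first principal component, which parts the regions, the ventral cKO samples also lay nearer the dorsal samples than the ventral controls did.

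Single samples decided several of these calls as well. At the preset correlation the choroid plexus and immediate early gene lists stayed called whichever 1 of the 6 samples was left out, but with all 6 samples neither was called with an estimated correlation (adjusted p = 0.818 for both with an estimated correlation). The interferon list was not called without control 41 (adjusted p = 0.0903). For ependymal markers, ventral calls were lost without control 49 (0.364) or cKO 64 (0.157). For meningeal fibroblast markers, ventral calls were lost without control 49 (0.218), control 50 (0.0603), cKO 40 (0.135) or cKO 64 (0.25), and the ventral marker list without control 41 (0.222), control 49 (0.13), cKO 40 (0.114) or cKO 63 (0.0831). With the choroid plexus score of each sample as a covariate, a setting chosen after the data were seen, none of these 6 lists was called. This follows by construction for choroid plexus markers, ventral (adjusted p = 0.946). The direction turned for ependymal markers, ventral (0.946), and meningeal fibroblast markers, ventral (0.395). It was kept for activity-regulated immediate early genes, ventral (0.0549), interferon response, ventral (0.0783), and ventral hippocampus markers, ventral (0.301). The score itself differs strongly between the ventral genotypes, and among the cKO samples only cKO 63 lies near the controls. The adjusted values thus rest largely on that sample. A lost call therefore does not show that choroid plexus content accounts for a list.

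**Figure D2:**
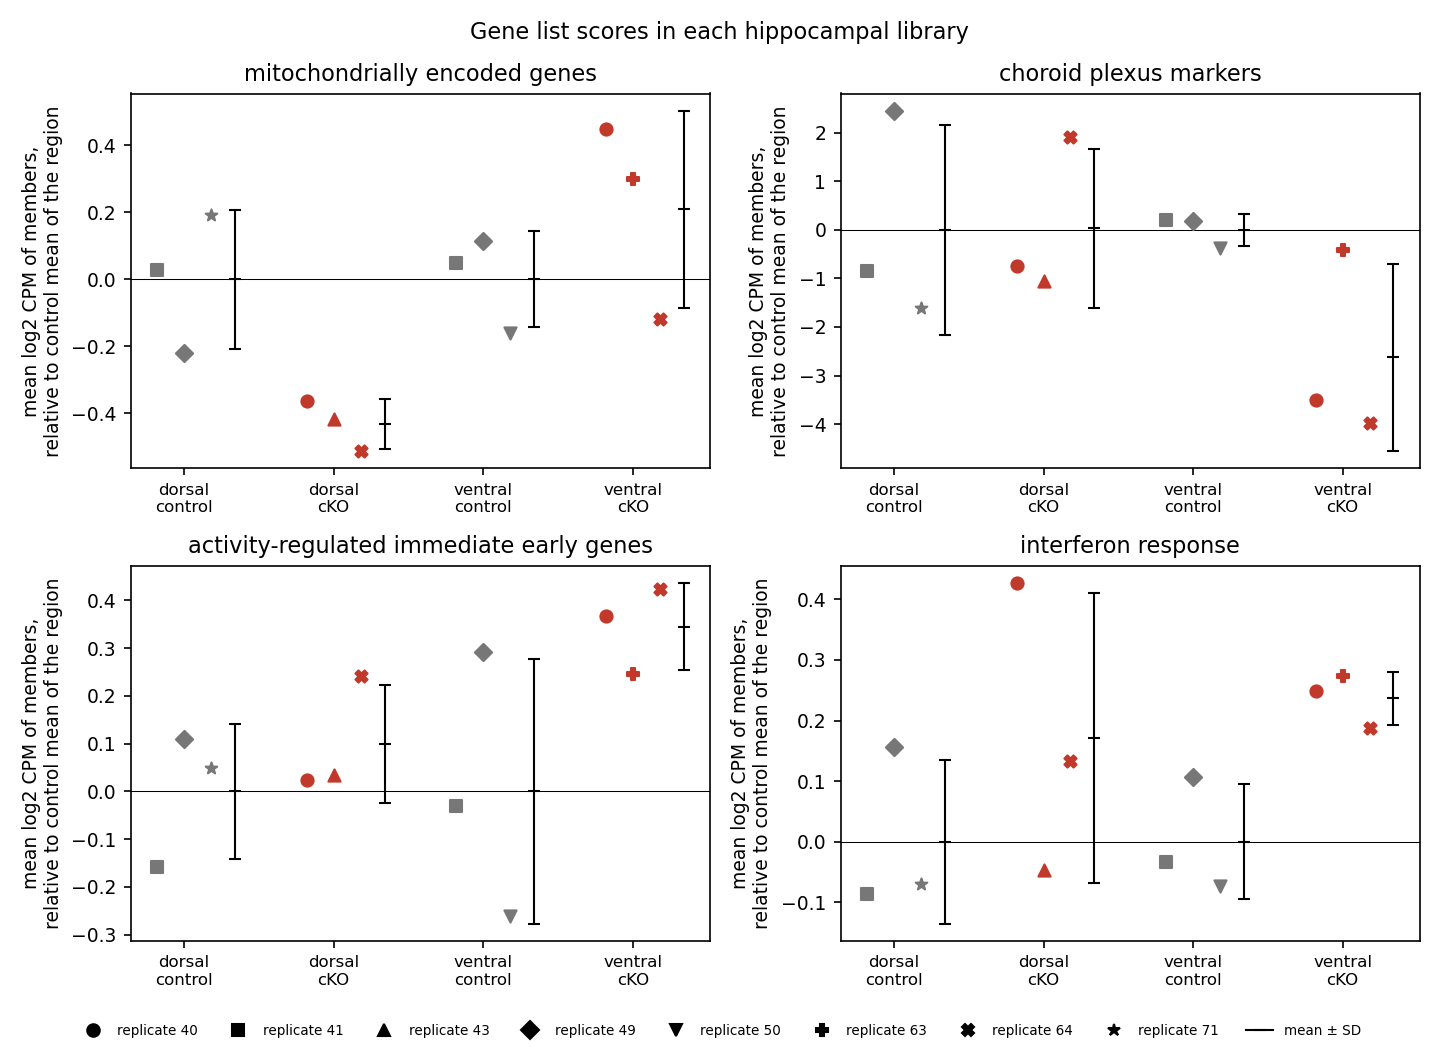
Scores of 4 gene lists in each of the 12 samples, as the mean log2 CPM of the list's members relative to the control mean of the same region; marker shapes give the replicate number, grey marks controls and red marks cKO, and bars give the mean and SD of 3 samples. The mitochondrial scores of the dorsal cKO samples lie below all dorsal controls, and the choroid plexus scores spread from -3.97 to -0.42 within ventral cKO and from -1.60 to 2.45 within dorsal control.

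By gene, Cadm4 (ENSMUSG00000054793; chromosome 7, 24482023 to 24504539), an adhesion molecule of axon and glia contacts, had the lowest ventral p, at 64.41 ± 2.81 CPM in cKO and 39.73 ± 4.06 CPM in control samples (SD, n = 3; 0.69 ± 0.11, SE). Higher means in cKO were also found for the homeobox gene Mkx (0.99 ± 0.19), the zinc finger factor Klf6 (0.49 ± 0.10), the pseudogene Gm7172 (0.57 ± 0.12; reads shared with its parent gene make it uncertain), the G-protein regulator Rgs20 (0.60 ± 0.13) and the kinase gene Hipk4 (0.63 ± 0.14). Lower means were found for Ezr, which links membranes to actin (-0.58 ± 0.12), Itpripl1 (-1.34 ± 0.29) and the endocytic adaptor gene Epn3 (-1.43 ± 0.32). edgeR's quasi-likelihood test called 0 of 15102 genes (smallest adjusted p = 0.527), with 1092 at an unadjusted p under 0.05 against 755 expected by chance, and limma-voom called 0. DESeq2 called 9 genes: Cadm4, Egr1, Eif4a2 and Klf6 rose, and Pomc, Slc4a2, Cab39l, Itpripl1 and Epn3 fell, with DESeq2 adjusted p from 0.00181 for Cadm4 to 0.0492. Without a filter on low counts edgeR called 302 ventral genes, and without ventral cKO 63 it called 55, of which 53 were lower. Among the ventral cKO samples, cKO 63 alone had a choroid plexus score near the controls (-0.42, with the lowest at -3.97). Lower genes in this comparison are therefore not parted from a difference in choroid plexus content. In simulated data of this depth, 31.3% of genes changed 1.5-fold and 71.6% of genes changed 2-fold were recovered.

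The authors' deposited tables give a further view of both comparisons, tested by the authors. At a false discovery rate under 0.05, the authors' deposited table for the dorsal hippocampus holds 166 genes, 41 higher and 125 lower in cKO, and that for the ventral hippocampus 543 genes, 287 higher and 256 lower. Their marks for up or down, which need a log2 fold change beyond 1 in size as well, are given in the authors' deposited tables to 12 and 8 dorsal and to 53 and 90 ventral genes. In the authors' deposited tables Lrpprc (-0.63, false discovery rate 1.23e-08) leads the dorsal genes named here and Cadm4 (0.68, 4.68e-10) the ventral ones, while Tet3 has a false discovery rate of 0.543 (dorsal) and 0.831 (ventral). Of the authors' calls, 154 dorsal and 494 ventral genes were tested here, each with the same sign, and 153 and 486 of them had an unadjusted p under 0.05 in edgeR's quasi-likelihood test. A likelihood ratio test on the separate runs, with the run as a covariate and chosen after the data were seen, called 236 and 772 genes here, including 165 and 538 of the authors' calls. Its log2 fold changes correlated with those of the authors' deposited tables at 0.9998 in each region. The authors' counts and false discovery rates thus appear to treat repeat runs of one sample as replicates.

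The 2 deposited tables share 25 called genes, against 3.4 if the lists were independent over all 26787 genes in both. That value is likely too low, since most calls fall among genes that passed the filter here. Some animals also occur in both tables on the reading above. Of the 25, 1 has the same sign in both, the phosphodiesterase gene Pde10a (0.36 dorsal, 0.34 ventral in the authors' deposited tables). Lower in dorsal and higher in ventral cKO in the authors' deposited tables were, among others, synaptophysin (Syp, -0.36 and 0.43), the vesicle fusion protein gene Vamp2 (-0.51 and 0.33) and the secretogranin gene Scg2 (-0.30 and 0.62). The list of presynaptic vesicle genes, which holds Syp and Vamp2, was not called in the dorsal, ventral or interaction comparison (limma camera, adjusted p = 0.496, 0.975 and 0.906), and 26 of its 34 members had a higher mean in dorsal cKO. Mcam (-0.46 and 1.27), Mt3 (-0.47 and 0.58) and St3gal5 (-0.57 and 0.39) had the same pattern in the authors' deposited tables, and Nufip2 the opposite one (0.26 and -0.26).

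**Figure D3:**
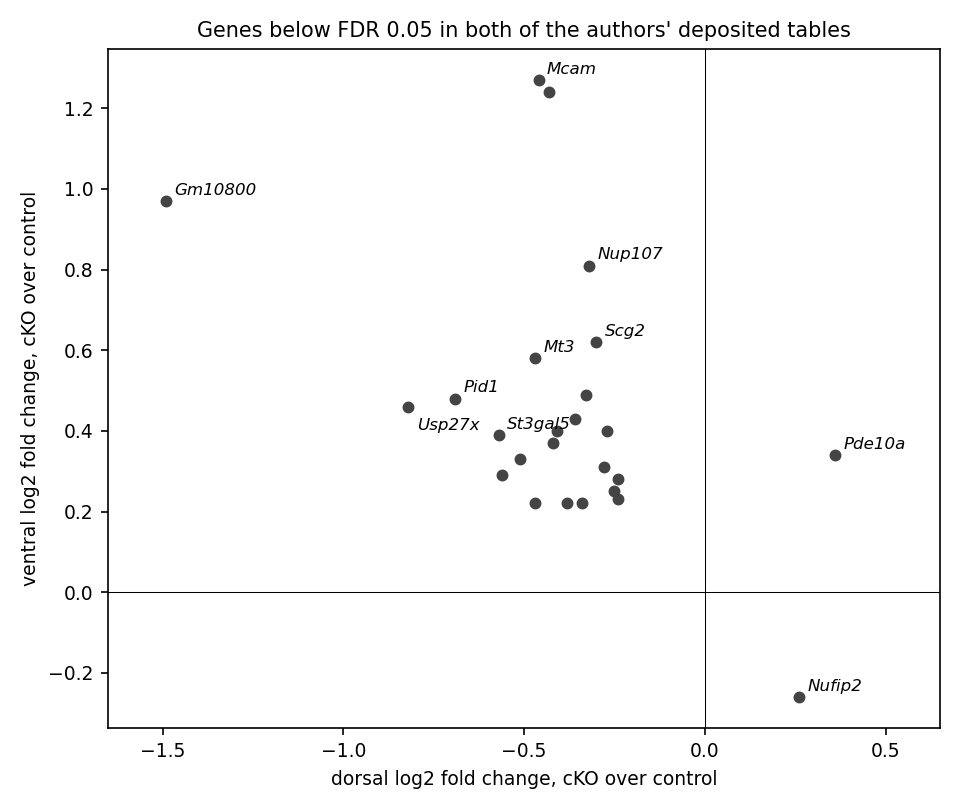
Log2 fold change, cKO over control, in the dorsal (horizontal axis) and ventral hippocampus (vertical axis) for the 25 genes below a false discovery rate of 0.05 in both of the authors' deposited tables; each point is a gene. Pde10a has the same sign in both regions, and the other points lie in the quadrants of opposite sign.

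Whether the genotype effect differed between the regions was tested as an interaction over all 12 samples (ventral minus dorsal). The 5 genes with the lowest p all had a positive interaction: Cadm4 (0.91 ± 0.14, log2 ± SE), the pseudogene Gm2830 (0.79 ± 0.15), the insulin signalling adaptor gene Pid1 (1.19 ± 0.24), Mkx (1.31 ± 0.26) and Mt3 (1.03 ± 0.21). By lists, the mitochondrial transcripts (median difference 0.58, adjusted p = 9.19e-08), ribosomal proteins (0.14, 5.32e-05), nuclear oxidative phosphorylation genes (0.07, 0.0173) and immediate early genes (0.23, 0.0184) had a more positive effect in the ventral region, and choroid plexus (-1.11, 5.32e-05) and ependymal markers (-0.74, 0.00248) a more negative one. None was called with an estimated correlation (limma camera, adjusted p = 0.949 for all 6 with an estimated correlation). Adjusted over the list alone, 7 mitochondrial members passed and 0 of the other 5 lists, and adjusted over all genes 0 did. With the replicate number as a block, which rests on fewer samples, the immediate early (limma camera adjusted p = 0.138) and oxidative phosphorylation lists (0.0808) were not called. The meningeal markers then were (0.00114), though not with an estimated correlation (adjusted p = 0.917 with an estimated correlation).

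edgeR's quasi-likelihood test called 0 of 16414 genes for the interaction (smallest adjusted p = 0.125, and 0.339 with the replicate number as a block), with 1307 at an unadjusted p under 0.05 against 821 expected by chance. limma-voom called 0 and DESeq2 34, all with a positive interaction, including Mt3 (DESeq2 adjusted p = 0.00289), Lrpprc, St3gal5 and Scg2. Without a filter on low counts edgeR called 13 genes. It called 4 without dorsal cKO 40, 3 without ventral control 41 and 1 without dorsal cKO 64. In simulated data 44.8% of interactions of 2-fold and 13.4% of 1.5-fold were recovered. Across the 16414 genes, the dorsal and ventral log2 fold changes had a Pearson correlation of -0.081 and a Spearman correlation of -0.117 (covariance -0.00564), and 44.8% of genes had the same sign. Genes are not independent replicates, so no p is given. The Pearson value was -0.251 without dorsal control 49, 0.069 without dorsal control 71 and 0.012 without dorsal cKO 64.

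The regions themselves, compared over both genotypes (6 samples each), differed in many genes. Known ventral markers were higher in the ventral samples: the copine gene Cpne7 was at 797.4 ± 79.6 CPM against 249.3 ± 21.7 CPM in the dorsal samples (SD, n = 6; log2 1.68 ± 0.08, SE), and the transcription factor Nr2f2 (1.67 ± 0.09), the gastrin-releasing peptide gene Grp (1.83 ± 0.11), Dlk1 (2.54 ± 0.20) and Dcn (2.50 ± 0.15) rose likewise. Of the 11 tested ventral markers 9 passed, and Etv1 (0.01 ± 0.07) and Calb2 (0.00 ± 0.27) did not. Of 7 dorsal markers, Lct (-2.01 ± 0.22), Lefty1 (-0.60 ± 0.15) and Pantr1 (-0.52 ± 0.09) were lower in the ventral samples, while Nov (0.93 ± 0.12) and Gpc4 (0.56 ± 0.13) were higher there, against the name of their list. Spink8 (-0.14 ± 0.12) and Wfs1 (0.06 ± 0.17) did not pass. The largest changes toward the ventral side among genes of at least 1 CPM were Dio3, which inactivates thyroid hormone (16.35 ± 4.12 against 0.7398 ± 0.396 CPM, 4.43 ± 0.25), Tnni3k (3.31 ± 0.34), the predicted genes Gm29771 (3.28 ± 0.38) and Gm44186 (3.15 ± 0.30) and the retinoid receptor gene Rxrg (3.10 ± 0.16). Toward the dorsal side they were 4921539H07Rik (-2.81 ± 0.23), the chemokine gene Cxcl5 (-2.47 ± 0.30), Gm10925 (-2.14 ± 0.69), the sodium channel subunit gene Scn4b (-2.03 ± 0.16) and Lct. Gm10925 is a pseudogene with reads that can be shared with copies, and its value moved between -2.43 and -0.61 when single samples were left out. With the replicate number as a block, Gm10925 (-1.02, edgeR adjusted p = 0.325), Lefty1 (-0.45, 0.161) and the ventral markers Efnb2 (0.38, 0.128) and Htr2c (0.71, 0.0591) did not pass; with that number as a random effect Gm10925 did not (-0.87, 0.451).

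Oligodendrocyte markers were lower in the ventral samples, with 18 of 19 passing (median -1.36, limma camera adjusted p = 2.87e-27, and adjusted p = 0.032 with an estimated correlation). The myelin basic protein gene Mbp was at 1375 ± 131 CPM against 3538 ± 313 CPM in the dorsal samples (-1.36 ± 0.08), and the myelin-associated glycoprotein gene Mag at 123.7 ± 7.74 against 343.5 ± 42.8 CPM. Precursor markers ranked lower as a list (adjusted p = 0.000746, and 0.054 with an estimated correlation). Of the 10 members 7 had a lower mean in the ventral samples and 3 a higher one. The 5 that passed were all lower, among them Olig1 (-0.63 ± 0.06) and Sox10. Whether precursor cells were fewer was not tested. The ventral marker list was called higher (adjusted p = 5.29e-11, and adjusted p = 0.0144 with an estimated correlation). With the replicate number as a block, neither it nor the oligodendrocyte list was called with an estimated correlation (adjusted p = 0.45 for both with an estimated correlation). That fit rests on the numbers found in both regions alone, so it holds less data. Thalamus markers were lower in the ventral samples (adjusted p = 1.01e-05; 0.0638 with an estimated correlation), with 4 of 11 passing over all genes and 9 adjusted over the list alone, among them Plekhg1 (-1.38 ± 0.13) and Prkcd. Imprinted genes were higher (adjusted p = 0.000618; 0.0638 with an estimated correlation), with 10 of 37 higher and 2 lower over all genes, among them Nnat (1.48 ± 0.16). Nuclear oxidative phosphorylation genes were higher (adjusted p = 7.68e-07; 0.368 with an estimated correlation), with 10 of 90 passing over all genes.

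The remaining 5 lists called between regions each had an adjusted p of 0.451 with an estimated correlation. Glucocorticoid receptor targets (10 of 30 lower, adjusted p = 0.00146), immediate early genes (10 of 39 lower and 2 higher, 0.00146), interferon response genes (4 of 27 lower, 0.00146) and microglia markers (3 of 20 lower, 0.0203) ranked lower in the ventral samples. GABAergic interneuron markers ranked higher (5 of 25 higher and 1 lower, 0.0292), with Nos1 at 1.21 ± 0.10 and Pvalb, the parvalbumin gene, at -0.46 ± 0.09. Adjusted over the list alone, 18 oligodendrocyte, 9 ventral and 5 precursor markers passed, as over all genes. On that basis 3 oxidative phosphorylation, 12 higher and 2 lower imprinted, 11 glucocorticoid, 16 lower and 2 higher immediate early, 5 interferon, 3 microglia, and 5 higher and 1 lower interneuron genes passed. With the replicate number as a block, microglia markers were not called (adjusted p = 0.0543), meningeal (0.0299) and blood genes (0.000151) were, and no list was called with an estimated correlation (smallest adjusted p = 0.45 with an estimated correlation).

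edgeR's quasi-likelihood test called 2313 of 16414 genes between the regions, 1094 higher in the ventral and 1219 higher in the dorsal samples. With the replicate number as a block it called 1411, 610 and 801 in these directions, of which 1323 were shared with the fit without the block. That block rests on the numbers found in both regions alone, so fewer calls can come from less data as well as from pairing. Simulated changes of 1.5-fold were recovered in 53.7% and of 2-fold in 85.1% of genes.

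**Figure D4:**
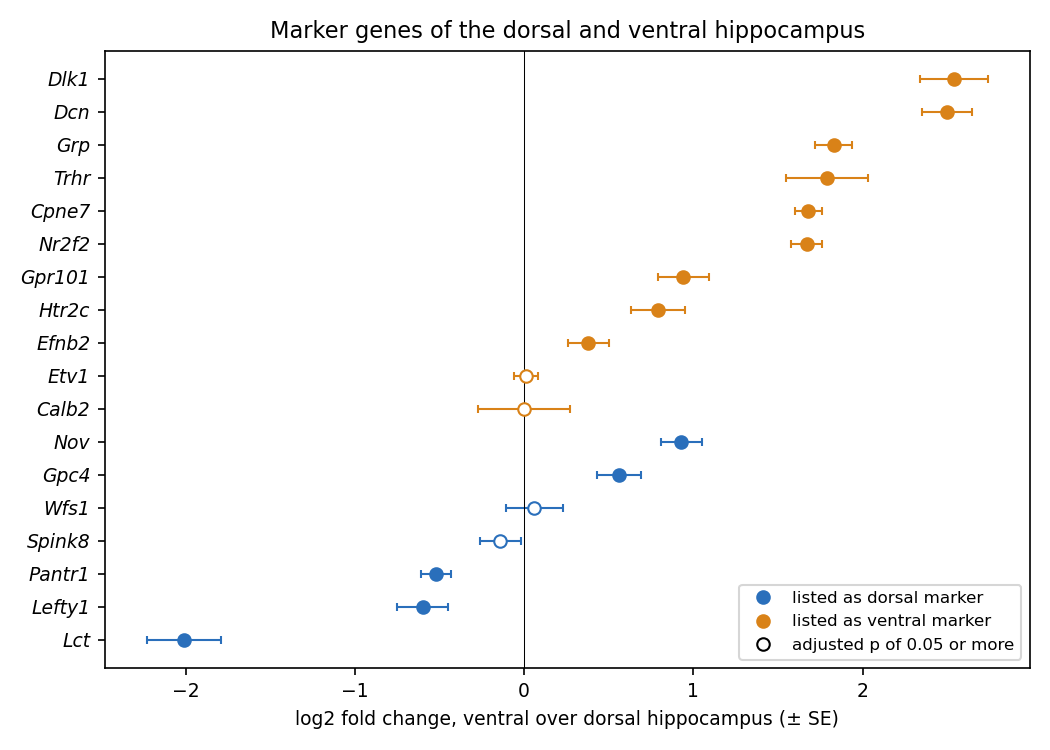
Log2 fold change, ventral over dorsal hippocampus, of the tested dorsal and ventral marker genes, with SE (6 samples per region); filled points passed an adjusted p of 0.05 in edgeR's quasi-likelihood test and open points did not. Dlk1 lies highest at 2.54 and Lct lowest at -2.01, and the dorsal markers Nov and Gpc4 lie above 0.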

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

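The tests below chosen only after the result was seen are the split counts for single genes by genotype (also those of DESeq2 and of edgeR without a filter) and for the interaction, the region splits that part all pairs, the range of the choroid plexus score and the dorsal choroid plexus difference. The 6 gene lists whose genotype effect differed between regions in the interaction test stand out for a closer look: mitochondrially encoded genes (median ventral minus dorsal log2 difference 0.58, limma camera adjusted p = 9.19e-08), choroid plexus markers (-1.11, 5.32e-05), cytosolic ribosomal proteins (0.14, 5.32e-05), ependymal markers (-0.74, 0.00248), nuclear oxidative phosphorylation genes (0.07, 0.0173) and immediate early genes (0.23, 0.0184). None was called with an estimated correlation (adjusted p = 0.949 for each with an estimated correlation).

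Choroid plexus markers were lower in ventral cKO, by -2.63 on the score. Uneven amounts of choroid plexus carried along at dissection may account for this, since the score ranged over 4.05 among the 3 dorsal controls alone and over 2.96 among the dorsal cKO samples. It ranged over 3.55 among the ventral cKO samples, but over only 0.59 among the ventral controls. Outside the marker lists, 81.9% of the 210 other genes lower in the authors' deposited ventral table rose with the score among dorsal samples of one genotype, against a median of 50.5% and a highest value of 63.8% in expression-matched random sets, and 29.5% of the genes higher in that table did. These genes thus followed the score, but among the dorsal samples only control 49 and cKO 64 had high scores. The tracking rests largely on them. Both also stood apart from the other dorsal samples on the second principal component (24.3 and 23.7). Anything else that they share could give the same tracking. It would hold as well if genotype lowered choroid plexus content, so it does not favour dissection as the cause. A lowering of choroid plexus transcripts by Tet3 ablation stays open: the dorsal cKO samples differed from the dorsal controls by 0.03, with SDs of 1.63 and 2.16, too wide to decide. By edgeR's log2 fold changes all 13 tested members were lower in dorsal cKO (median -0.52), 0 of them at an unadjusted p under 0.05. They move together (estimated correlation 0.975), so their shared sign does not decide it either. The markers came from lists fixed before the data were examined, and Enpp2 is shared with the oligodendrocyte list and Sostdc1 with that of CA3 and CA2.

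The correlation of genotype effects between regions was -0.081 across genes, but 0.069 without dorsal control 71, 0.012 without dorsal cKO 64, -0.251 without dorsal control 49 and -0.188 over genes of at least 10 CPM, and 24 of 25 genes called in both of the authors' deposited tables had opposite signs. Of the 16 assignments of the animals to genotypes, 3, the real one included, gave a correlation as negative; the 15 other than the real one ran from -0.124 to 0.15 (median 0.038), and 16 are too few for a share under 0.05. The 25 genes, signed by their ventral effect, moved together within groups, at 0.388 against a median of 0.076 and a 95th percentile of 0.15 for expression-matched sets (percentile 100 of 10000 sets). That could come from a shared axis along which samples of one group differ, whatever its origin, including RNA quality or dissection. The 25 genes were picked from these same samples, while the random sets were matched on expression alone. Genes that respond together to genotype could move together too, so the co-movement does not decide between these. A region-specific effect of Tet3 loss stays open and was not tested apart from such an axis.

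The run-level test counts repeat runs of one animal as replicates by design, so its p-values overstate the evidence. How much of its counts rests on that was asked with other splits of the animals. In the dorsal hippocampus the 9 other splits of the 6 animals called a median of 193 genes against 236 for the real one. In the ventral hippocampus the median was 115 against 772, so how many ventral calls rest on it stays undecided. In the dorsal hippocampus 5 of 10 splits called as many, with a highest other of 1185 where controls 41 and 71 stood with cKO 40, several times the real count, which points to a structure of the samples apart from genotype. In the ventral hippocampus 2 of 10 did, with a highest other of 799. With 10 splits the share cannot fall under 0.05, and a real genotype effect in the ventral region stays open.

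For the other counts, edgeR's quasi-likelihood test gave as many genes in 10 of 10 splits in the dorsal (real 0, highest other 0) and in 10 of 10 in the ventral hippocampus (real 0, highest other 4). As many lists were called in 6 of 10 dorsal splits (real 6, highest other 10) and in 2 of 10 ventral splits (real 6, highest other 8). These 10 splits are too few for a share under 0.05. DESeq2 called up to 74 genes in other dorsal splits (real 22) and up to 40 in other ventral splits (real 9). Without a filter on low counts edgeR called up to 346 (real 94) and 245 (real 302), and the dorsal highest is several times the real count. For the interaction, 100 of 100 splits drawn from 200 gave as many genes (real 0, highest other 4). Every split reaches a count of 0, so this count and those of the quasi-likelihood test by region say nothing about chance. For the region comparison 1 of 100 did, the real one (2313, highest other 71). Among all 32 splits that part each pair of samples from one animal, 1 did, again the real one (highest other 6), so chance can be excluded there.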

How the results depend on the processing

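Settings chosen only after the data were seen are the likelihood ratio test on runs, the choroid plexus score as a covariate and the removal of 4 samples; a change of sign is judged on values rounded to 2 decimals, a rule also set after the values were seen. The genotype counts of 0 (dorsal, ventral, interaction) stayed at 0 with other scalings, a stricter filter, limma-voom, a threshold of 0.1 and, for the regions, all groups in 1 fit, and the largest median shift of a scaling was -0.061. They became 22, 9 and 34 with DESeq2, 94, 302 and 13 without a filter on low counts, and 193, 714 and 1033 (region by genotype interaction) with runs as separate libraries, where genes differing between regions numbered 4742. The likelihood ratio test on runs gave 236 and 772. Run 1 alone gave 1 and 3 genes, a region count of 1149, and turned dorsal Tet2 (0.13), ventral Dlk1 (0.02) and Gm10925 (0.25). Run 2 alone gave 4 ventral genes, 1 interaction and a region count of 1345, and turned dorsal Tet3 (-0.02), dorsal Tet1 (-0.07) and Wfs1 (-0.04); run 3 alone turned ventral Tet3 (-0.05). Single runs hold fewer counts and tested fewer genes; otherwise the cause was not tested. The replicate block gave a region count of 1411 and turned Wfs1 (-0.09); the other calls it ended are given beside the results. The planned test of neighbouring genes was not run on the calls of edgeR's quasi-likelihood test, which were 0, nor on those of DESeq2 or of edgeR without a filter. No paired analysis was possible because the genotype groups within a region share no replicate number; the region and interaction comparisons were blocked instead. With the choroid plexus covariate there were 8 dorsal genes and 2 ventral lists, neither among the 6 called without it, and ventral Tet3 (-0.21), Rsph1 (0.08), Col1a1 (0.25) and the lists of ependymal markers, ventral (limma adjusted p = 0.946), and meningeal fibroblast markers, ventral (0.395), turned. Without dorsal control 49, dorsal cKO 64 and ventral cKO 40 and 64, picked for their choroid plexus scores, ventral cKO 63 stood alone and was assumed to vary like the other groups, so the ventral and interaction values rest on 1 sample. There were 10 dorsal genes, 3 interactions, a region count of 1132 and 3 ventral lists, and ventral Tet3 (-0.23), Col1a1 (0.06), Wfs1 (-0.06), Etv1 (-0.08) and the meningeal list (0.808) turned. Lists called numbered 0 and 0 with an estimated correlation, 0 and 0 with fry, and 10 in the ventral region on ranks. The correlation of genotype effects between regions was -0.188 over genes of at least 10 CPM. Leaving out 1 sample, counts ran from 0 to 25 (dorsal, 25 without control 49), 0 to 55 (ventral, 55 without cKO 63), 0 to 4 (interaction, 4 without dorsal cKO 40) and 1838 to 2261 (region). Lists called ran from 2 to 9 (dorsal, 2 without control 71) and from 3 to 8 (ventral, 3 without control 49). Tet3 ran from 0.10 to 0.28 in the dorsal and -0.09 to 0.20 in the ventral hippocampus, Wfs1 from -0.09 to 0.20, Etv1 from -0.04 to 0.05 and the correlation from -0.251 to 0.069. The following counts are over the settings that keep every sample or remove the 4, and they leave out Tet3. Of single named genes, 1159 values kept direction and call, 149 gained a call, 18 lost it and 11 turned. Of list values 34 kept both, 35 lost the call and 3 turned. Single named genes of the genotype and interaction comparisons had no call to lose. For them a kept call means staying uncalled, so the count of 1159 says little about how firm their values are. At this depth, dorsal changes of 1.5-fold were recovered in 40.3% of simulated genes.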

Other observations

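Genes of the stress axis did not move as a list in either region (limma camera, adjusted p = 0.855 dorsal and 0.975 ventral), but several members had low unadjusted p. In the ventral hippocampus the precursor of ACTH and beta-endorphin, Pomc, was at 2.594 ± 0.351 CPM in cKO and 9.58 ± 5.11 CPM in control samples (SD, n = 3; log2 fold change -1.83 ± 0.42, SE), a DESeq2 call. Crhr2, a receptor of the urocortins, was at -1.16 ± 0.30. The oxytocin receptor gene Oxtr was at -0.74 ± 0.20 in the ventral and 0.93 ± 0.31 in the dorsal hippocampus, and the PACAP gene Adcyap1 at 0.60 ± 0.26 and 0.51 ± 0.19. Of the 16 tested ventral members, 12 had a higher mean in cKO and 4 a lower one. Among the lower ones, 3 (Pomc, Crhr2 and Oxtr) passed edgeR's quasi-likelihood test adjusted over the list alone. That adjustment does not cover the choice of this list among the 42 tested. Adjusted over all genes, no member passed in either region. Choroid plexus markers differed between the same ventral groups (-2.63 on their score). Of genes outside the marker lists that were lower in the authors' deposited ventral table, 81.9% rose with that score among dorsal samples of one genotype. That share covers genes such as Oxtr, but whether each of these 3 genes follows the score was not looked at singly. The share rests largely on dorsal control 49 and cKO 64, the dorsal samples with high scores.

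Interneuron and synapse genes gave further values short of the threshold. In the dorsal hippocampus 4 of 24 GABAergic interneuron markers had an unadjusted p under 0.05, all lower in cKO (list adjusted p = 0.116): Pvalb (-0.35 ± 0.10), the developmental factor Lhx6 (-0.57 ± 0.19), Sst (-0.24 ± 0.09) and Npy (-0.28 ± 0.12). In the ventral hippocampus Nos1 was at -0.43 ± 0.11 and Sst at 0.26 ± 0.11. Postsynaptic genes were not called as a list (adjusted p = 0.631 dorsal, 0.165 ventral and 0.181 for the interaction), and at an unadjusted p under 0.05 there were 1 higher and 4 lower in dorsal cKO and 5 higher in ventral cKO. Camk2a, whose promoter drives the Cre transgene, was at -0.32 ± 0.13 in the dorsal hippocampus, and Shank2, a postsynaptic scaffold, at -0.35 ± 0.14 in the dorsal and 0.54 ± 0.16 in the ventral hippocampus. Cacng2, an auxiliary AMPA receptor subunit, was at 0.44 ± 0.14 in the ventral hippocampus. The NMDA receptor subunit gene Grin1 was at 0.43 ± 0.12 in the dorsal hippocampus. Of 19 microglia markers in the ventral hippocampus, 17 had a mean above that of the controls (median 0.18), 0 at an unadjusted p under 0.05 in edgeR's test. The list was not called (limma camera adjusted p = 0.0566, and adjusted p = 0.818 with an estimated correlation).

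The Cre line came from a mixed background, so DNA of the other strain around the transgene could place called genes near each other; the use of the authors' calls here was chosen after the result was seen, since edgeR's quasi-likelihood test called none. The authors' calls were used where the gene was tested here and had a position outside the mitochondrial genome. Of these, 145 dorsal genes made 15 pairs within 1 Mb, with a median of 15 in 10000 random draws (one-sided permutation p = 0.563). The 493 ventral genes made 164 pairs, with a median of 180 (permutation p = 0.838). Within 100 kb p was 0.164 and 0.632, and within 5 Mb 0.276 and 0.158. The bound fixed beforehand, no more pairs than the median draw, was met in both regions. Both values lie within the spread of the draws, so a bound at the 5th percentile was set after the values were seen and the matter is left undecided; a short segment would add few pairs.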
